A study of Homo sapiens with 3 samples.

How the data were processed

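Dimethyl sulfate mutational profiling reads RNA structure in 1 number per nucleotide. Dimethyl sulfate methylates the Watson-Crick face of adenosine and cytidine where it is not paired or covered, and reverse transcriptase misreads the methylated base, so a high mutation signal marks an accessible A or C. Human 28S ribosomal RNA of HEK293 cells, a line derived from embryonic kidney, was measured in 3 libraries. The cell line field of the labels gives HEK293 and the growth protocol gives HEK293T/17, a derivative that carries the SV40 large T antigen. Per the labels, cells received 10 µM cycloheximide, 10 µM of the probe RiboBright or the same volume of the solvent DMSO for 30 min. RNA was extracted with TRIzol, reverse transcribed with TGIRT-III from random hexamers and made into libraries with the NEBNext Ultra II workflow, per the labels' protocols. The dose and duration of dimethyl sulfate treatment are not given in the sources used here.

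The deposited values are a signal per nucleotide of 28S rRNA, with 3 decimals, never negative, given for A and C alone. Bowtie2, cutadapt and the build hg38 are named in the submitters' processing notes, without versions or roles. The mutation counter, the normalization, any coverage minimum and any subtraction of background are not given in the sources used here. From the values, a scaling within each library and base can be read: the mean of the values ranked 2 to 10% from the top was 0.987 on A and 0.994 on C in DMSO, 0.988 and 0.995 in cycloheximide, and 0.990 and 0.993 in RiboBright. A signal of 1 therefore stands for a highly reactive nucleotide of that base in that library, and a change shared by all nucleotides would then not be visible. The values carry no read counts or coverage, so the depth of each library is not given and no counting interval is given. In some stretches low values of a library recur or fall to exactly 0, so a change there may rest on few reads. An A or C without a value was treated as not measured, and an exact 0 was kept as a value. No library without dimethyl sulfate is analysed here, so natural modifications that are misread by reverse transcriptase remain in the signal. The table of the whole series and each library's own file held identical values, and no column of per-sample values was left out.

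Positions count from the 5′ end of 28S rRNA as the deposited table numbers them. The sarcin-ricin motif began at position 4599, which places its cleavable adenosine at A4605, the number this adenosine has in human 28S rRNA. The table spans 5070 nt. In the RefSeq gene table for GRCh38.p14, RNA28SN5 has this length and lies on a sequence without an assigned chromosome in that table, from 113348 to 118417. RNA28SN1 (5066 nt), RNA28SN2 (5054 nt) and RNA28SN3 (5055 nt) lie on chromosome 21, and RNA28SN4 (5077 nt) on chromosome 22. The copies are nearly identical and reads cannot be assigned to one of them, so a position describes the pool of copies. The 28S sequence was not matched to a genome sequence.

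All comparisons were made on A and C. Each library was scaled to DMSO by the median of its values above 0, with factors of 0.945 for cycloheximide and 0.912 for RiboBright. On the log2 scale these factors moved all values by -0.08 and -0.13, and every change is relative to that shift. Ratios are log2 of scaled value plus a pseudocount of 0.0104, which is 10% of the DMSO median, so they understate changes at low levels. A position was called higher or lower where the ratio was at least 2-fold and the higher of both scaled values reached 0.24025, the 75th percentile of DMSO. This rule of size is not a test. With 1 library per treatment no difference has a replicate check, no p-value is given, and the called positions compare libraries, not treatments.

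The positions named for each comparison are the 10 called positions with the largest rise and the 10 with the largest fall in scaled signal, the E-site nucleotides and other functional sites whatever their values, and the 2 windows of 100 nt with the highest and the 2 with the lowest median ratio. Any other named position is marked in the text as chosen after its value was seen. The E-site region is every A and C in 4331 to 4351 and 4360 to 4380. Its median was ranked among 10000 random sets of the same size matched on DMSO signal. Windows needed at least 10 A or C with a value. The call rule, the regions, the naming rule and most alternatives were fixed before the data were examined. They covered scaling, pseudocount, level floor, size of change, positions at the ends, region width, window size and summary statistic. Alternatives that restrict positions by missing values, leave out C4341, scale A and C separately or scale over the positions above 0 in all 3 libraries were chosen after the data were seen. The planned sites in 18S rRNA are not analysed here, and the planned counts on G and U were left out because those bases carry no value.

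For the correlation of both responses, 1000 sets of unchanged libraries that share a control were simulated, and 1000 more for the overlap of calls, which were added after the data were seen. The call rule was tested on simulated data in 20 simulations of 200 planted falls each, with noise drawn from the observed ratios at like signal. For cycloheximide (2200 positions) it found 92.0% of 2.5-fold, 99.9% of 4-fold and 100% of 8-fold falls, and it called 6.57% of unplanted positions past the level floor. For RiboBright (1838 positions) it found 86.3%, 99.2% and 100%, and it called 7.09% of unplanted positions. That noise includes any real change, so the latter shares are upper estimates. The planted falls were placed only where the DMSO signal reached the floor, and those positions are left out of the latter shares. Positions that reach the floor only through a rise therefore weigh more in them than in the observed shares. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots Matplotlib 3.10.9.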

Results

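The mutation signal of human 28S rRNA was compared between HEK293 cells treated with cycloheximide, RiboBright or DMSO, with 1 library for each treatment. Cycloheximide is an inhibitor of translation elongation that binds the E site of the large ribosomal subunit, where the deacylated tRNA leaves. RiboBright is a probe whose structure the labels do not give. The series addresses the organization and movement of ribosomes, and these libraries ask which 28S nucleotides each compound covers or exposes. The rRNA has 797 A and 1695 C. Values were present at 2220 of these 2492 positions in DMSO (89.1%), at 2264 in cycloheximide (90.9%) and at 1838 in RiboBright (73.8%). RiboBright lacked mainly cytidines, with 1111 C listed against 1450 in DMSO, and its 1838 positions were all listed in the other libraries too. Over those positions, 114 values were exactly 0 in RiboBright (6.20%), against 11 in DMSO (0.598%) and 9 in cycloheximide (0.490%).

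Adenosines had a median signal of 0.133 in DMSO, 0.1395 in cycloheximide and 0.136 in RiboBright. Cytidines had medians of 0.077, 0.082 and 0.079 in the same order. The most reactive position of every library was A1322, which carries a natural N1-methyl group, at 17.791 in DMSO, 18.729 in cycloheximide and 18.991 in RiboBright. Across the 1838 common positions, which are not independent replicates, log2 signal in cycloheximide and DMSO had a Pearson correlation of 0.952. The correlation was 0.880 for RiboBright and DMSO and 0.879 for RiboBright and cycloheximide.

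C4341, the cytidine of the E site known as the footprint of cycloheximide, lost most of its signal under cycloheximide. Its signal was 2.564 in DMSO, 33.3 times the median cytidine, and 0.212 in cycloheximide, 2.59 times the median. After scaling, 7.82% of the DMSO signal was left, a log2 ratio of -3.61. Among cytidines its rank went from 17 of 1450 in DMSO to 386 of 1490. The scaled difference of -2.36 was larger in size than at any other position, ahead of a difference of 2.13 at C883, which was chosen after its value was seen. C883 had a signal of 5.945 in DMSO and 8.541 in cycloheximide, a log2 ratio of 0.44 that did not reach the 2-fold rule.

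Of 2200 positions compared between cycloheximide and DMSO, 588 reached the level floor, and 88.9% of these lay within 1.5-fold. The rule called 27 positions (4.59%), and it called 6.57% of unplanted positions in libraries simulated with the observed spread. The simulated share leaves out planted positions, all past the floor in DMSO, so it is not directly comparable with 4.59%. Those simulations draw on the same ratios, called positions included, so these shares cannot tell real changes from noise. Of the 27, 16 were higher and 11 lower. Cytidines made up 24 of the 27 and 359 of the 588 positions past the floor. Signals at named positions are the deposited values, and log2 ratios and differences follow scaling. After C4341, the largest called falls were at A893, from 0.620 to 0.227, at C901, from 0.433 to 0.057, at C3045, from 0.541 to 0.212, and at C931, from 0.367 to 0.125. C537, C3059, C1151, C446 and A466 were also lower, with log2 ratios from -2.24 at C1151 to -1.37 at C446. C1151 fell from 0.253 to 0.048. In cycloheximide C1130 and C1137, chosen after their values were seen, also had 0.048, so the fall at C1151 may rest on few reads. Near C901, cycloheximide had 0.057 at C904 and 0 at C903 and C907. Near C795 it had 0 at C794, C796 and C797. These neighbours were also chosen after their values were seen, and the changes at C901 and C795 may likewise rest on few reads. The largest called rises were at C795, from 0.136 to 0.583, at C3502, from 0.254 to 0.686, and at C447, from 0.148 to 0.535. C3499, C3431, C436, C531 and C3443 were higher by log2 ratios from 1.15 at C531 to 1.69 at C3431. C3558 rose from 0.296 to 0.639. C3396 was listed at 0 in DMSO and at 0.27 in cycloheximide, so no fold is given.

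These calls were unevenly placed. Within 25 nt of an A or C that lacked a value in some library, 25 of 198 positions past the floor were called (12.6%), against 2 of 390 elsewhere (0.513%). Those 2 were C4341 and C3558. A value in all 3 libraries was present at 5 of the 27 called positions, which were C4341, C931, C3558 and, chosen after their values were seen, C938 and C984. With the floor at the 90th percentile of DMSO, C4341 was the 1 position called.

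RiboBright gave the same largest change. The signal at C4341 was 0.146 in RiboBright, 1.85 times the median cytidine and rank 356 of 1111. After scaling, 5.19% of the DMSO signal was left, a log2 ratio of -4.16 and a difference of -2.43. The largest differences after it, at A1964 (-1.39), C1594 (-0.81) and C92 (-0.81), were fractions of high signals and stayed within 1.5-fold. A1964 is also among the largest falls in scaled signal under cycloheximide, at -0.99, and these positions were chosen after their values were seen.

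**Figure D1:**
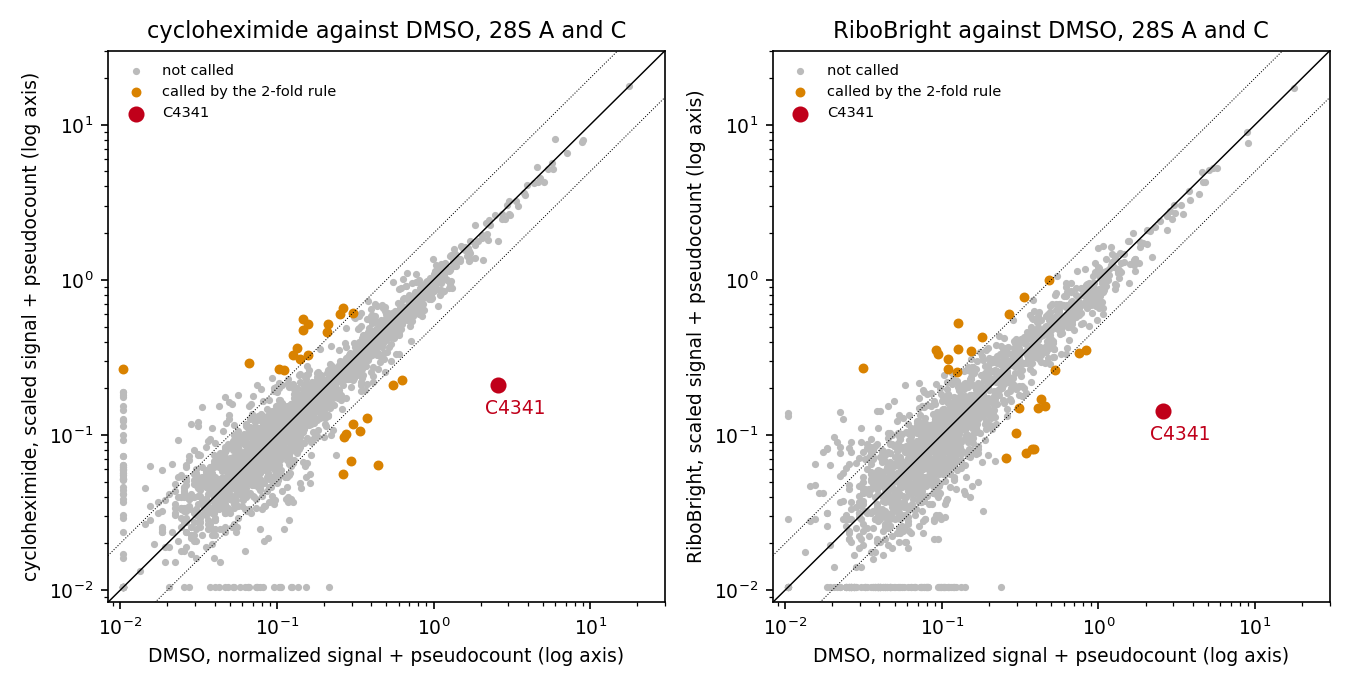
Scaled signal plus pseudocount at each A and C of 28S rRNA in cycloheximide (left) and RiboBright (right) against DMSO, both axes logarithmic, with 1 point per position, a solid line of equality and dotted lines at 2-fold. Called positions are orange, and C4341 in red, at 2.564 in DMSO, lies far below the line in both panels, at log2 ratios of -3.61 and -4.16.

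Between RiboBright and DMSO 1838 positions were compared, 498 reached the floor and 26 were called (5.22%), 13 higher and 13 lower. The rule also called 7.09% of unplanted positions in libraries simulated with the observed spread. That share again leaves out planted positions, all past the floor in DMSO, so it is not directly comparable with 5.22%. Those simulations draw on the same ratios, called positions included, so these shares cannot tell real changes from noise. Among the 450 positions past the floor in both comparisons with DMSO, 13 were lower and 4 higher under RiboBright, against simulated means of 9.88 (95% between 4 and 16) and 8.51 (95% between 3 and 15) for unchanged libraries. This filter drops rises that reach the floor only through RiboBright, while falls reach it through DMSO. The counts of 13 and 4 are therefore not a balance of directions. Of the positions past the floor 81.9% lay within 1.5-fold. Cytidines made up 9 of the 13 lower positions and adenosines 9 of the 13 higher ones, while 271 cytidines and 227 adenosines were past the floor. C4029 fell from 0.820 to 0.378 and had 0.80 in cycloheximide. C1182 fell from 0.737 to 0.360, C3566 from 0.379 to 0.077 and C3033 from 0.443 to 0.158. C931, C1197, A2725, C3567 and A2231 were lower by log2 ratios between -2.23 at C931 and -1.01 at A2725. RiboBright signals were 0.077 at C931 and 0.073 at C1197. Nearby, A932 had 0.07 and C1188 had 0.073 in RiboBright, both chosen after their values were seen. The falls at C931 and C1197 may therefore rest on few reads. C1875 rose from 0.476 to 1.08 and A1254 from 0.322 to 0.838. C984 rose from 0.116 to 0.562, C946 from 0.258 to 0.652, and A1324, which is 2 nt from the methylated A1322, from 0.082 to 0.374. A3663, C941, A935, A956 and A2105 were higher by log2 ratios between 1.23 at A3663 and 3.10 at C941. All but A3663 lie within 25 nt of a missing value. Around C984, RiboBright had 0 at C983 and C986, 0.079 at C981 and 0.08 at C985. Around C941 it had 0 at C940 and A944 and 0.067 at A943. These neighbours were chosen after their values were seen. The rises at C984, C941 and A935 may therefore rest on few reads.

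The robust SD of the log2 ratio past the floor was 0.388 for RiboBright against DMSO and 0.233 for cycloheximide against DMSO. Over positions listed in all 3 libraries the latter was 0.193. Called positions made up 16.2% of those within 25 nt of a missing value (12 of 74) and 3.30% elsewhere (14 of 424). Stretches 751 to 1000 and 3501 to 3750 held 5 of the 13 rises and 5 of the 13 falls, respectively. The share of higher calls was 50.0% and moved with the scaling, to 70.3% of 37 calls without scaling, 64.5% of 31 with scaling by the 90th percentile and 62.5% of 32 with A and C scaled separately. It turned toward falls with a lower floor, with 41 higher and 51 lower at the DMSO median and 82 higher and 203 lower (28.8% higher) without a floor.

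At the same concentration and incubation time, both compounds left a low signal at C4341. The log2 ratio of RiboBright to cycloheximide was -0.55, from scaled signals of 0.133 and 0.200, and did not reach the 2-fold rule. A ratio at least that large was seen at 28.6% of the 668 other positions of like mean signal, within a factor of 2. The middle 95% of ratios at those positions ran from -1.16 to 1.22, so a difference of that size between the compounds was not detectable with these libraries.

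Over 1838 positions compared between RiboBright and cycloheximide, 486 reached the floor and 28 were called, 19 higher and 9 lower in RiboBright. The balance turned with other settings, to 45 higher and 47 lower with the floor at the DMSO median, 79 higher and 196 lower without a floor, and 2 higher and 5 lower at 3-fold. The lower positions were C1197, C4029, C3566, A2231, C1182, C3033, C3567, C3739 and A3596. C1197 had the largest called fall, from 0.523 in cycloheximide to 0.073 in RiboBright, and C4029 fell from 0.80 to 0.378. RiboBright also had 0.073 at C1188 and 0 at C1190 to C1193, chosen after their values were seen. The fall at C1197 may therefore rest on few reads. Among called positions, A408 had the largest rise over cycloheximide, at 1.156 against 0.488. It was followed by C4693 at 0.893 against 0.307 and C936 at 0.953 against 0.414. Differences in scaled signal at positions not called reached -0.63 and 1.18, larger than at any called position. A1868, A1294, C946, A163, A1324, A956 and A3663 were higher by log2 ratios from 1.02 at A1868 to 3.11 at A1324. Within 25 nt of a missing value 12 of 72 positions were called (16.7%), against 16 of 414 elsewhere (3.86%).

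**Figure D2:**
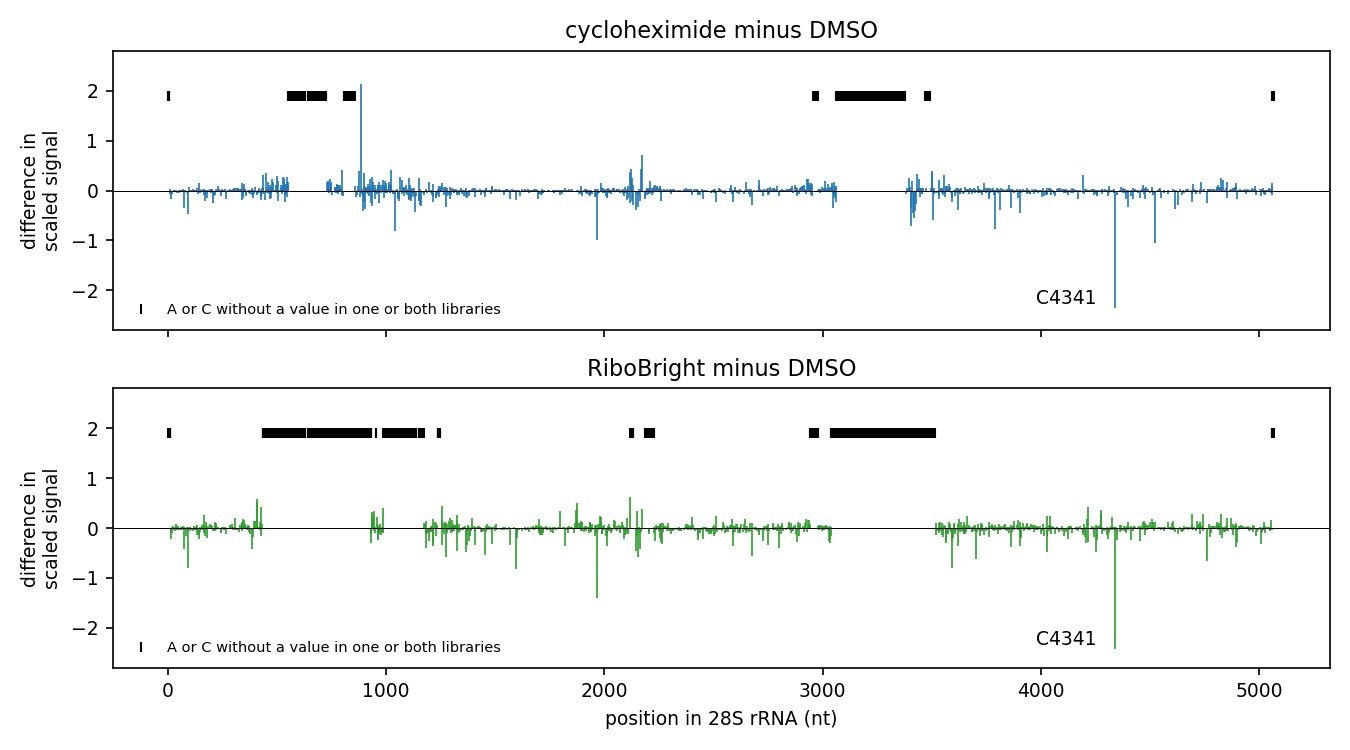
Difference in scaled signal from DMSO at each A and C along 28S rRNA (position in nt) for cycloheximide (top) and RiboBright (bottom), with black ticks at A and C without a value in one or both libraries. The deepest line in both panels is C4341, at -2.36 and -2.43, and the tall rise in the top panel is C883, at 2.13.

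C4341 was the only called A or C of the E-site region, under either compound. The 22 A and C of the E-site region had a median log2 ratio of -0.01 for cycloheximide against DMSO, at percentile 62.8 of 10000 matched random sets. The median was -0.18 for RiboBright against DMSO, at percentile 26.4, and -0.15 for RiboBright against cycloheximide, at percentile 30.1. The RiboBright medians moved to -0.07 against DMSO without scaling and to -0.03 against cycloheximide with 5 nt on each side. Of the 21 positions other than C4341, 0 were called in these comparisons, and 5 of them reached the floor against DMSO under cycloheximide and 4 under RiboBright. Their differences from DMSO lay between -0.092 and 0.071 under cycloheximide and between -0.232 and 0.065 under RiboBright. The largest of their log2 ratios to DMSO in size was -1.20, at C4332 under RiboBright, where signals of 0.045 and 0.015 lay below the floor. C4342, the adjacent cytidine, had a low signal in every library, at 0.036 in DMSO, 0.032 in cycloheximide and 0.017 in RiboBright. C4349, the second most reactive position of the region in DMSO, had 1.008 in DMSO, 0.969 in cycloheximide and 0.851 in RiboBright. C4332, C4342 and C4349 were chosen after their values were seen. The E-site nucleotides U4340, G4370 and G4371 carry no value.

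**Figure D3:**
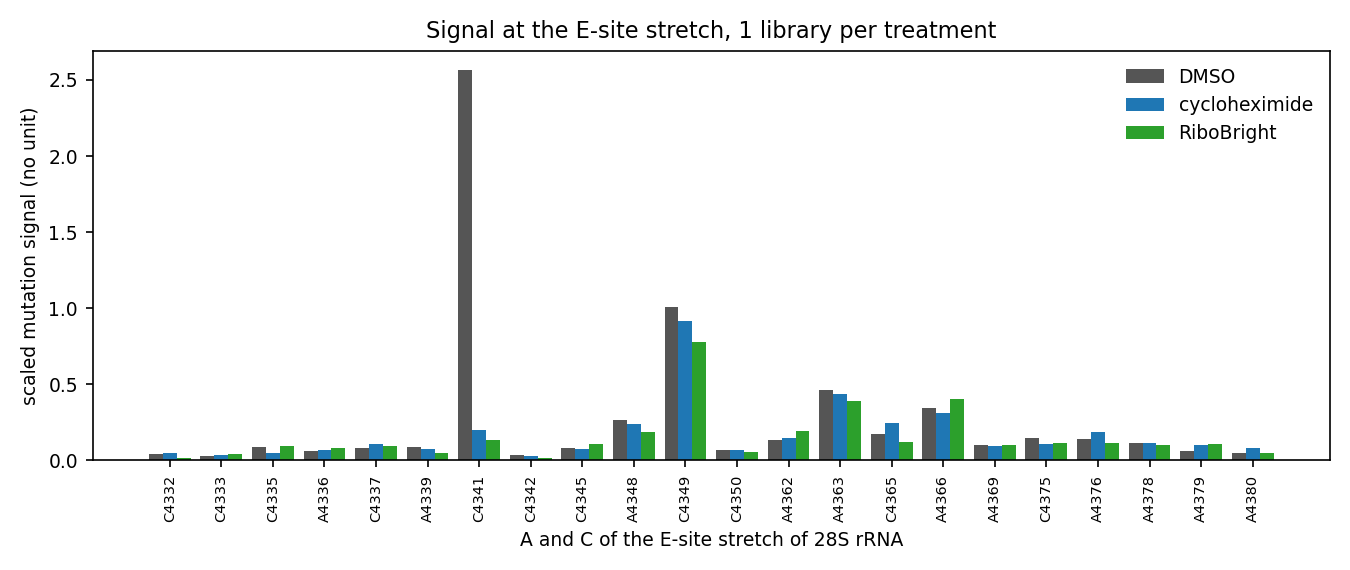
Scaled signal (no unit, linear axis from 0) at the 22 A and C of the E-site region in DMSO (grey), cycloheximide (blue) and RiboBright (green), with 1 bar per library and no error bars. C4341 stands at 2.564 in DMSO, 0.200 in cycloheximide and 0.133 in RiboBright, while C4349 stays near 1 in DMSO and at 0.776 in RiboBright.

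Nucleotides of the peptidyl transferase centre, where peptide bonds form, were not called in any comparison. A4397 had a signal of 0.142 in DMSO, 0.151 in cycloheximide and 0.124 in RiboBright. C4398 had 1.267, 0.989 and 1.517 in the same order, with log2 ratios to DMSO of -0.43 and 0.13. A4548 had 0.389, 0.259 and 0.377, and its log2 ratio of -0.65 under cycloheximide was the largest in size among these sites. The sarcin-ricin loop, a binding site of elongation factors, had 0.480, 0.542 and 0.474 at A4605. U4452, U4531 and the methylated U4530 carry no value. At A1322 the log2 ratios to DMSO were -0.01 and -0.04, and the 20 most reactive common positions other than C4341, A1322 among them, had ratios from -0.24 to 0.21 under cycloheximide and from -0.40 to 0.12 under RiboBright.

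Within 10 nt of these sites, medians over the A and C were ranked among random windows. For the peptidyl transferase sites under cycloheximide they were -0.13 at A4397 (percentile 21.2), -0.20 at C4398 (10.5), -0.21 at U4452 (9.74), -0.18 at U4531 (14.1) and -0.03 at A4548 (43.5). Under RiboBright they were 0.05 (73.5), -0.07 (52.4), -0.03 (59.9), 0.23 (91.7) and 0.0069 (67.6) in the same order. The windows overlap between A4397 and C4398, and U4530 shares the 7 A and C of U4531. For RiboBright against cycloheximide all 5 medians were above 0, from 0.11 at A4548 (percentile 78.1) to 0.23 at C4398 (91.3). Around A4605 the median log2 ratio was -0.09 under cycloheximide (percentile 31.2) and -0.12 under RiboBright (percentile 45.1). Around A1322 the 14 positions had a median of -0.19 under cycloheximide (percentile 13.0), 0.23 under RiboBright (percentile 92.3), and 0.40 for RiboBright against cycloheximide (percentile 96.3).

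In windows of 100 nt, cycloheximide was lowest against DMSO at 1101 to 1200, with a median log2 ratio of -0.20, and at 4601 to 4700, with -0.19. It was highest at 701 to 800, with 0.33, and at 901 to 1000, with 0.32. A value was missing in some library at all 47 A and C of 701 to 800, at 32 of 63 in 901 to 1000 and at 36 of 49 in 1101 to 1200, and at 0 in 4601 to 4700. The middle of the 47 windows, between quartiles, ran from -0.08 to 0.05. RiboBright was lowest against DMSO at 1101 to 1200, with -1.15 over 13 A and C, and at 3501 to 3600, with -0.78 over 43 A and C. RiboBright values of 0 made up 5 of 13 in the former window and 15 of 43 in the latter, against 0 and 2 in DMSO. RiboBright was highest at 401 to 500, with 0.27 over 14 A and C, and at 2901 to 3000, with 0.25 over 26 A and C. In these windows 30 of 44 and 24 of 50 A and C lacked a value in some library. The quartiles of its 42 windows were -0.18 and -0.0036. Against cycloheximide, RiboBright was lowest at 901 to 1000 (-0.67, with 8 of 31 RiboBright values at 0 and 0 in cycloheximide) and 1101 to 1200 (-0.63), and highest at 401 to 500 (0.46, over the same 14 A and C) and 4501 to 4600 (0.20). The lowest window moved to 3501 to 3600 with means in place of medians.

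C4341 and C931 were called lower, and C984 higher, under both compounds, in comparisons that share the DMSO library. The RiboBright signals at C931 and C984 may rest on few reads. Across 1838 positions the log2 ratios of cycloheximide and RiboBright to DMSO had a Spearman correlation of 0.236 and a Pearson correlation of 0.281. Unchanged libraries simulated with a shared control gave a mean Spearman correlation of 0.289, with 95% of values between 0.245 and 0.333. The observed 0.236 lay below that range, so the simulated libraries did not reproduce it. The observed covariance was 0.112 and the simulated mean 0.115 (95% between 0.090 and 0.139), a difference of -0.0031. The noise of these simulations was taken from the observed ratios, which hold any real response, and rests on equal noise in DMSO and cycloheximide, so a shared response was neither shown nor excluded. Among 450 positions past the floor in both comparisons, 2 were lower under cycloheximide and 13 under RiboBright, and both of the former, C931 and C4341, were shared. Unchanged libraries simulated with the shared control gave a mean of 0.308 shared falls (95% between 0 and 2), and independent lists would give 0.0578. For rises the counts were 3 and 4, with C984 shared, against a simulated mean of 0.327 (95% between 0 and 2) and 0.0267 for independent lists. The simulated overlaps draw on the same ratios, the falls at C4341 and C931 included, and the 1 control library cannot be split.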

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

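Alternatives based on missing values, leaving out C4341, separate scaling of A and C, and scaling over positions above 0 in all 3 libraries were chosen after seeing the data. C4341 stayed lower and called in all 14 alternatives, from -3.67 to -3.37 for cycloheximide and from -4.26 to -3.82 for RiboBright. RiboBright against cycloheximide there ran from -0.59 to -0.45 and was not called. Only the scalings and pseudocounts could move the ratio at C4341, and the other alternatives could alter only whether it was counted or called. The number of called positions, in the order cycloheximide against DMSO, RiboBright against DMSO and RiboBright against cycloheximide, went from 27, 26 and 28 to 92, 92 and 92 with the floor at the DMSO median, 1, 5 and 7 at the 90th percentile, and 196, 285 and 275 without a floor. It was 65, 90 and 88 at 1.5-fold, 10, 9 and 7 at 3-fold, and 2, 14 and 16 away from positions without a value. Over positions with a value in all 3 libraries, cycloheximide had 5. Fewer positions qualify under a higher floor, a larger fold or a restriction, by construction. The E-site median for cycloheximide was -0.11 with 5 nt on each side. The correlation of both responses was 0.204 with a level floor and 0.281 as Pearson, and the cause of these moves was not tested. Means in place of medians, in DMSO, cycloheximide and RiboBright, were 0.324, 0.326 and 0.324 on A and 0.254, 0.263 and 0.255 on C, because a few positions are far above the median. The window values moved too, and the cause was not tested. With means, the highest window of cycloheximide was 0.52 (701 to 800) and the lowest -0.44 (1101 to 1200), the lowest of RiboBright -0.93 (1101 to 1200), and the lowest of RiboBright against cycloheximide -0.85 (3501 to 3600 in place of 901 to 1000). With windows of 50 nt, the lowest were -0.32 for cycloheximide (1 to 50) and -1.05 for RiboBright against cycloheximide (3551 to 3600). The other extremes against DMSO also changed place, with the highest at 2901 to 2950 for both compounds and the lowest of RiboBright at 3551 to 3600. Scaling by G and U, the correlation on G and U, the E-site region over all bases and other coverage minimums were not run, since the values hold neither these bases nor coverage, and each library's own file was identical to the table. No paired analysis was possible because each treatment has 1 library, and no replicate could be left out. Depth is not given, so what it limits was not measured. The robust SD of RiboBright against DMSO was 0.94 in the lowest 25% of DMSO signal and 0.34 in the highest.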

Other observations

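The tests of coverage, noise, E-site binding, spread and depth in this part were chosen only after the results were seen, while scalings were planned except separate scaling of A and C and scaling over positions above 0 in all 3 libraries. Positions without a value gathered where 28S rRNA is rich in G and C. In RiboBright 14 of 51 windows of 100 nt lacked a value at 50% or more of their A and C, with a median GC content of 86%. In DMSO and cycloheximide 4 windows did, with medians of 88.5% and 89.5%. Windows with every A and C listed had a median GC content of 60% in RiboBright (31 windows) and 65.5% in DMSO and in cycloheximide (40 windows each).

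Near the natural methylation at A1322, RiboBright had a signal of 0.374 at A1324, against 0.082 in DMSO and 0.032 in cycloheximide. A1326, chosen after its value was seen, had 0.376 in RiboBright, 0.180 in DMSO and 0.145 in cycloheximide. C1875 and A1868 lie 7 nt apart and were both higher in RiboBright, at 1.08 and 0.801, than in DMSO, at 0.476 and 0.373, with A1868 called against cycloheximide and not against DMSO. C4029 was lower in RiboBright at 0.378, while DMSO and cycloheximide had 0.820 and 0.80, and it had no missing value within 25 nt.

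The fall of signal at C4341 under both compounds was weighed against 4 technical explanations. Thin coverage around C4341 is argued against by the 47 A and C within 50 nt, of which 0 lacked a value in any library, and by their median log2 change in size of 0.168 under cycloheximide and 0.269 under RiboBright, below 0.238 and 0.356 over all positions. Scaling left the ratio at -3.53 or lower in every scaling tried, and the fall was 3.05 times (RiboBright) and 3.32 times the largest change at any other position of its level or lower that passed the floor. That cut drops C883 (2.13, cycloheximide) and A1964 (-1.39, RiboBright), against -2.36 and -2.43 at C4341. Differences grow with level, which favours reactive positions. On the log2 scale C3396 reached 4.67 under cycloheximide, but it had 0 in DMSO and lies within 25 nt of a missing value. Its ratio therefore does not describe noise at the level of C4341. The 20 most reactive common positions other than C4341 had ratios from -0.24 to 0.21 under cycloheximide. Under RiboBright they ran from -0.40 to 0.12. These argue against the usual noise at that level, though with 1 library per treatment an error at 1 position was not excluded. A compound bound at the E site that covers C4341 may account for the fall, though no structure or competition is analysed here. The 4 fixed peptidyl transferase and sarcin-ricin nucleotides with values changed by at most 0.65 on the log2 scale. They would also stay unchanged with an odd DMSO value at C4341 alone, so they do not decide between these accounts. An odd DMSO library, high at C4341 by itself, cannot be told apart from such binding, since there is 1 DMSO library and both ratios share it.

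The 26 cycloheximide calls other than C4341 may come from thin coverage. Of these, 22 (84.6%) lie where RiboBright has no value, against 131 of the 588 positions past the floor (22.3%). Coverage itself is not analysed here, and a cycloheximide effect in those stretches was not tested separately.

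The wider spread of RiboBright than of cycloheximide against DMSO held away from missing values, with robust SDs of 0.354 and 0.180. A lower depth of the RiboBright library is a candidate explanation, since it has 114 values of 0 at the common positions, against 11 in DMSO and 9 in cycloheximide. The window at 3501 to 3600 held 15 of these zeros, and C3566 and C3567 lie in it with RiboBright signals of 0.077 and 0.153. A compound wide effect on 28S structure stays open and cannot be told apart from depth with 1 RiboBright library, since no repeat of the calls can be had.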
